A study of Mus musculus with 2 samples.

How the data were processed

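Biotin-labelled cRNA made with the Ambion MessageAmp kit from Trizol-extracted total RNA was hybridized to Illumina mouse beadchips, per the labels' protocols, with 1 array of normal fibroblasts (NF) and 1 of cancer-associated fibroblasts (CAF). The deposited values used here are linear probe intensities that the authors made with GenomeStudio, per the submitters' processing notes. Its version and settings are not given in the sources used here. From the values themselves, the intensities were background-subtracted (33.7% of NF and 37.5% of CAF probes lay below 0) and scaled to a shared mean of 230.7 on both arrays. A second deposited table of non-normalized signals with detection p-values was not used. Its 2 signal columns carry names that match no label of either sample, and columns were not assigned by order or value. The neqc analysis with detection p-values designed for that table therefore gave way to the procedure set beforehand for background-subtracted values.

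Without detection p-values, a detection limit was set per array from the values below 0. Mirrored about 0, they stand for the background distribution, so the 98th percentile of their sizes leaves about 1% of background above it. The limits were 10.1 (NF) and 10.5 (CAF), and this rule was chosen after the values had been seen. If background has a longer upper tail than lower tail, more than 1% of it passes. Intensities were raised to the limit where below it, log2-transformed and quantile-normalized with limma 3.58.1 in R 4.3.3. Lists and counts were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Arrays carry no read depth, and their number (1 per group) limits the precision.

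Probes were named from GEO's platform annotation. Of 45281 probes, 34885 had 1 gene symbol, 18 had several and were left out, and 10378 had none there and were not used. They name 19057 genes. Each gene was represented by its brightest probe (mean of both arrays) among those detected on at least 1 array. For a gene with all probes undetected on one array, the fold is a lower bound against the lowest normalized value of a detected probe there. Genes whose probes disagreed on detection (72) were in no count of 2-fold differences other than that of named genes past 2-fold. Mfap2, Slc7a11, Muc1 and Mcam were in that count. Names in the fixed lists were matched to RefSeq symbols of GRCm38.p6, through older names where these belonged to 1 gene, which matched 826 of 827 names to 811 genes. Of these, 730 had a named probe and 538 were measured. Coordinates were not used, because the array's build is not given in the sources used here.

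With 1 array per group no test was run and no p-value is given. Differences are described by size, with 2-fold as the threshold. For 28 gene lists and 12 lists of markers of other cell types, the median log2 difference of the measured members was set against 10000 random lists of the same size, drawn from the 10836 measured genes and matched on mean intensity in 20 bins. A list of at least 5 measured members was said to stand apart below percentile 2.5 or above 97.5. By chance 1.6 of 32 lists would, if the genes of a list varied independently, which genes of a pathway do not. Differences were also simulated from a normal distribution with the real standard deviation over the 10836 genes of this comparison. There 6% of unshifted lists of 15 genes stood apart, against 37.5% of lists shifted by 0.5 and 80% of lists shifted by 1 (log2). The shape of the real differences was not simulated, so these shares are not rates for the real lists.

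The gene lists, the 2-fold threshold, the random-list procedure and the rule for named genes were fixed before the data were examined. The bound for genes detected on 1 array, its omission where it would turn the direction, and the tolerances used to compare settings (0.58 log2 for a value, 0.05 for the correlation) were set afterwards. Named were the 12 highest and 12 lowest genes detected on both arrays (leaving out clone and predicted names), the 3 largest bounds in each direction, up to 4 members per list with the largest difference, the 3 brightest members of each marker list per array, and 10 fixed genes (Socs1, Igf1, Cxcr4, Acta2, Fap, Tgfbr2, Kras, Il6, Trp53, Cdkn2a). Alternatives were no scaling beyond the authors', 75th percentile scaling, cyclic loess, a limit leaving 5% of background above it, no detection filter, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, and unmatched random lists. Added after seeing the data were quantile normalization before the floor, a limit 3 times as high, offsets of 16 and 50 in place of the floor, and list medians with genes on 1 array at their bound. Cyclic loess was run as designed, over all probes. After its values had been seen, a cyclic loess fitted only on probes detected on both arrays was added, because 55.9% of probes tied at the floor on both arrays. The all-probe fit shifted probes of like intensity by amounts that differed by up to 6.00 (log2) within 1 of 20 intensity bins, against 0.15 in the added fit. The alternatives without background correction and with another normexp offset need the non-normalized table and were not run.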

Results

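Total RNA from 2 fibroblast preparations of mixed C57BL/6 and BALB/c mice was profiled on Illumina expression beadchips, which measure each transcript with one or more bead-bound probes. One array held cancer-associated fibroblasts (CAF) from pancreatic ductal adenocarcinoma of mice carrying a pancreas-directed Cre, an activated Kras allele and floxed Tgfbr2. The other held normal fibroblasts (NF) from mice with floxed Tgfbr2, wild-type Kras and no Cre. The question was which genes differ in expression between tumour-derived and normal fibroblasts. Each group had 1 array, so there was no replicate error, no test was possible, and every difference below compares these 2 arrays and not the 2 conditions. Intensities are the authors' background-subtracted values, and log2 differences are CAF minus NF after quantile normalization.

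Of 45281 probes, 18325 (40.5%) lay above the detection limit on the NF array and 16900 (37.3%) on the CAF array. They represented 10836 named genes, of which 8735 were detected on both arrays. Among these 8735 genes, 1124 were at least 2-fold higher in CAF and 947 at least 2-fold lower, so 54.3% of the genes past 2-fold were higher. This split followed the scaling between arrays. It was 38.1% higher with the authors' scaling alone and 64.1% with scaling to a shared 75th percentile, while the median of all genes moved from 0.03 to -0.15 and 0.20 (log2). A cyclic loess fit over all probes gave 1869 genes at least 2-fold higher in CAF, and an offset of 50 in place of the floor gave 588 higher and 490 lower. Another 770 genes were detected only in CAF and 1259 only in NF. The lower bound on the fold reached 2-fold for 310 of the former and 300 of the latter, so most lay near the limit. Across genes, which are not independent replicates, the arrays correlated at a Pearson r of 0.907. For 647 genes past 2-fold with 2 or more probes detected on both arrays, all probes pointed the same way in 568 (87.8%). Single other probes of such genes shared the direction in 89.7% of cases, against 50.4% when probes were shuffled between genes, and 57.7% both shared the direction and passed 2-fold.

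**Figure D1:**
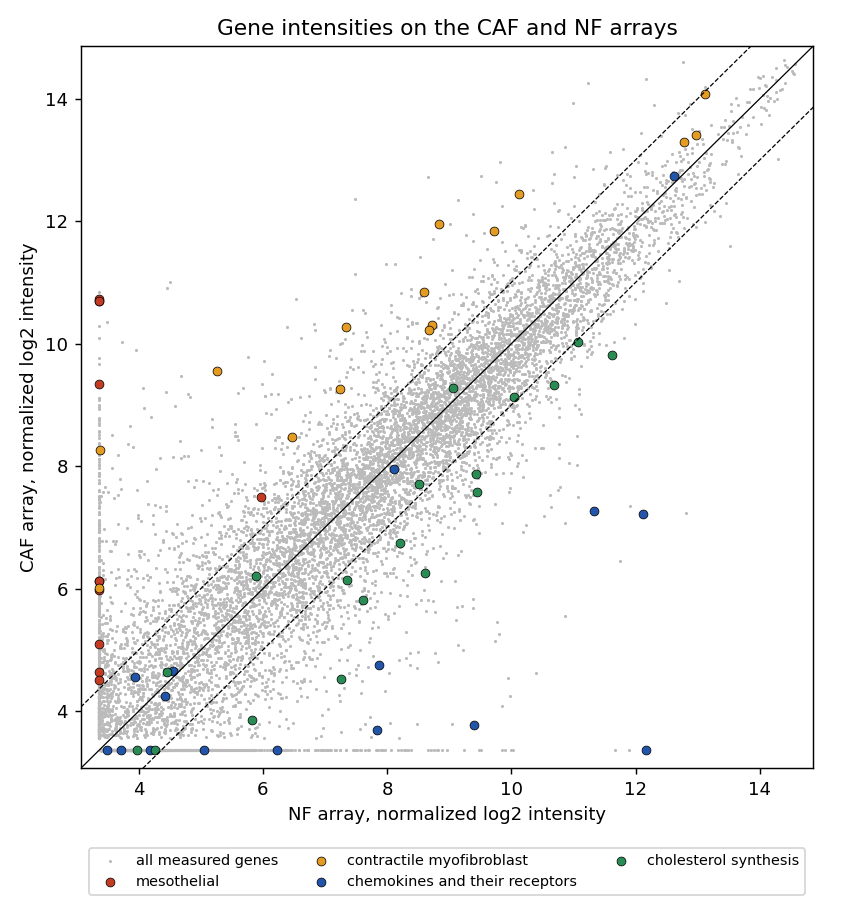
Normalized log2 intensity of each measured gene on the NF array (x axis) and the CAF array (y axis), with the solid line at equality and dashed lines at 2-fold. Of the mesothelial markers 10 lie on the floor of the NF array and Msln lies above it, contractile genes lie mostly above the upper dashed line, and 8 of 16 chemokine genes and 11 of 18 cholesterol synthesis genes lie at least 2-fold lower in CAF.

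Tgfbr2, the TGF-beta type II receptor gene that both genotypes carry in floxed form, was close to equal on the 2 arrays. Its brighter probe read 2434.3 in NF and 2983.2 in CAF (log2 difference 0.29), and a dim probe differed the other way (-0.51). Where these probes lie relative to the floxed part is not known here, so they do not check the genotype. Kras and Trp53 had no named probe and are not analysed here. Fap, which encodes fibroblast activation protein, was below the detection limit on both arrays.

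The genes with the largest differences included secreted factors, cell-surface proteins and matrix enzymes. Igfbp6, an IGF-binding protein, read 12 in NF and 1293.7 in CAF (log2 difference 6.86). Lims2, an adaptor of integrin adhesions, was higher by 6.50, Fxyd6 by 6.46, the glutathione transferase gene Gsta3 by 6.30, and Fgfr2, a fibroblast growth factor receptor, by 5.95. Nipsnap1 (5.21), Hs3st1 (4.93), the hyaluronan-degrading factor Cemip (4.88), the smooth-muscle gene Lmod1 (4.88), Efs (4.88), the monoglyceride lipase gene Mgll (4.81) and the junctional receptor gene Cxadr (4.78) completed the 12 highest. In the opposite direction, ceruloplasmin (Cp) read 1350.6 in NF and 21.5 in CAF (-5.77). Gas7 (-5.77), Igfbp5 (-5.73), the monocyte chemokine gene Ccl2 (-5.63) and stromelysin-1 (Mmp3, -5.57) were close to it. Lgi2 (-5.40), the glucocorticoid-activating enzyme gene Hsd11b1 (-5.32), the transcription factor gene Sox9 (-5.30), Pcolce2 (-5.26), Ccl7 (-4.89), Tro (-4.68) and Snhg11 (-4.62) followed. The largest bounds among genes detected on 1 array only were for Smpd3, Upk1b and Bnc1, at least 178-fold, 164-fold and 161-fold higher in CAF. Ccl9, Ankrd1 and Inmt were at least 389-fold, 323-fold and 276-fold lower. In 19 of the 24 genes detected on both arrays the dim side lay under 3 times the detection limit, so these folds are imprecise. With an offset of 50 in place of the floor, the 24 log2 differences ranged from 2.47 to 5.16 in size.

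Markers of mesothelium, the lining of the body cavities, were higher on the CAF array. Of 13 members with a named probe 11 were measured. All 11 were at least 2-fold higher, 10 of them detected only in CAF, and the median log2 difference was 2.76. Upk3b, a uroplakin of mesothelial cells, read 1646.6 in CAF and was below the limit in NF (at least 160-fold), and Cdh3, P-cadherin, was at least 62.8-fold higher. Mesothelin (Msln), detected on both arrays, was 2.88-fold higher. The keratin genes Krt8, Krt18 and Krt19, which this list shares with the epithelial one, were among the 11. The list median was at percentile 100 of 10000 random gene lists of matched size and mean intensity.

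Genes of the contractile apparatus, which myofibroblasts share with smooth muscle, were also higher in CAF. Of 15 measured members 12 were at least 2-fold higher and 0 were at least 2-fold lower, with a median log2 difference of 2.12 (4.34-fold, percentile 100). Desmin (Des) read 43.5 in NF and 728.2 in CAF (log2 difference 4.29), myosin light chain Myl9 was higher by 3.12, and transgelin (Tagln) by 2.94. Acta2, alpha smooth muscle actin, was higher by 0.96 on its brightest probe, which read 8604.3 and 18594. Its other 3 probes detected on both arrays gave 2.99, 4.01 and 4.42. The genes Actg2, Des, Lmod1 and Myh11 are shared with the pericyte and smooth muscle marker list. Its 8 measured members had a median of 2.11 (percentile 100), with 4 at least 2-fold higher and 1 lower. The 4 members counted as higher were the shared genes, so that count adds little that is separate from the contractile list. Mcam, which is not on the contractile list, was left out of the count because its probes disagreed on detection. It entered the median, and its 3 probes, dim or undetected in NF, were higher in CAF by 2.64, 2.91 and 4.36. Without a detection filter the pericyte and smooth muscle median was 0.0, since members below the limit on both arrays then count as equal. Notch3 was that lower member, at least 3.12-fold. The mesothelial markers were higher on the same array.

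Collagen genes were higher in CAF, whereas other matrix genes went both ways. Of 16 measured collagen genes 9 were at least 2-fold higher and 0 at least 2-fold lower (median 1.37, percentile 100). Col4a1 and Col4a2, which encode basement membrane collagen, were 8.84-fold and 9.27-fold higher, Col5a2 was 10.3-fold higher and Col8a2 at least 16.9-fold. Col5a2 read 10.8 in NF, just above the limit, so its fold is imprecise. Among 26 matrix glycoproteins and proteoglycans 5 were at least 2-fold higher and 8 lower (median -0.18, percentile 14.9, with a median of 0.06 under 75th percentile scaling). Mfap5, a microfibril component, was higher by 4.39 and Emilin2 lower (-3.20). Among 27 matrix proteases, inhibitors and crosslinkers 7 were higher and 4 lower (median 0.19, percentile 91.4). Timp3, a metalloproteinase inhibitor, was higher by 2.94 on its brightest probe and by 0.35 on its dimmest, and cathepsin K (Ctsk) was higher by 3.10. The fibroblast identity list had 4 members at least 2-fold higher and 5 lower of 18 (median -0.33, percentile 4.72). Thy1 was 5.59-fold higher, lumican (Lum) 5.74-fold lower, and Fbln1 and Dpt were detected only in NF, at least 38.3-fold and 15.1-fold. The mesothelial markers were higher on the array with the higher collagens.

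**Figure D2:**
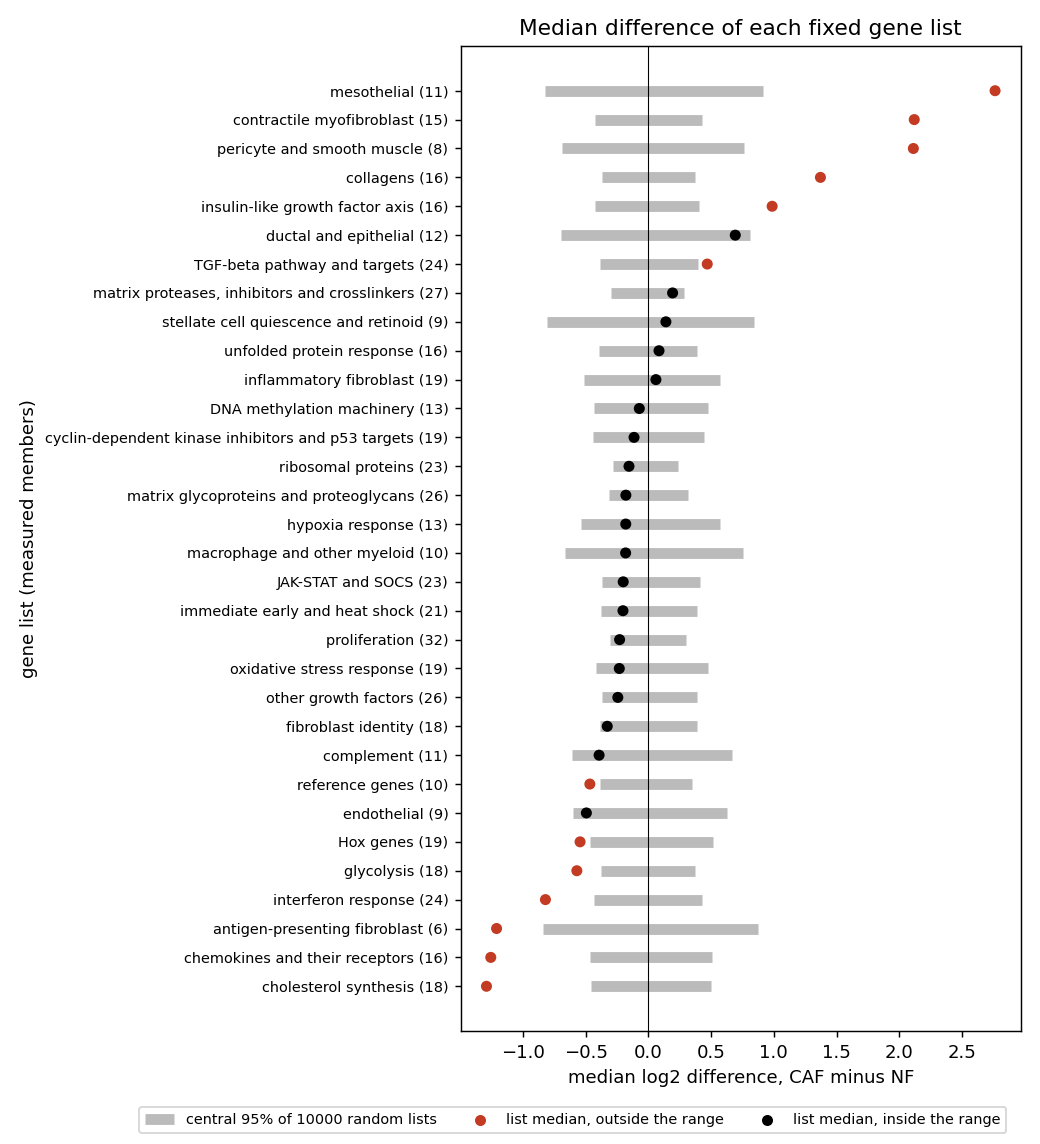
Median log2 difference, CAF minus NF (x axis), of each gene list with at least 5 measured members (y axis, number of members in parentheses). Points are list medians and grey bars the central 95% of 10000 random lists matched on size and mean intensity. Medians of 13 of the 32 lists lie outside their bar, 6 higher and 7 lower in CAF.

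Chemokine genes were lower in CAF. Of 16 measured chemokines and receptors 8 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.26 (percentile 0.0), or -1.06 with genes detected on 1 array at their bound. The median was -0.78 under the cyclic loess fit over all probes and 0.0 without a detection filter, where undetected members count as equal. Ccl9 read 4592.9 in NF and 6.7, below the limit, in CAF. Ccl2 was 49.4-fold lower, Ccl7 29.7-fold and Ccl5 17.7-fold. Cxcr4, the receptor of Cxcl12, was dim in NF at 20.6 and below the limit in CAF, at least 1.54-fold lower. Markers of other cell types differed between the same arrays, with 11 of 11 mesothelial markers at least 2-fold higher in CAF. The acinar genes Rnase1 (156.7 in NF, -10.3 in CAF) and Cela1 (219.7 and 23) and the endothelial gene Plvap (240.2 and 4.8) were lower. Only 4 of 19 acinar markers with a named probe were measured. Of 9 measured endothelial markers 2 were at least 2-fold lower and 0 higher (percentile 7.29). The brightest, Flt1, was close to equal (819.9 in NF and 784.2 in CAF). Markers of myeloid cells went both ways. Of 10 measured, 2 were at least 2-fold higher and 3 lower (median -0.18, percentile 26.3), with Cd14 2.32-fold lower, Lyz1 1.99-fold higher and Lyz2 1.74-fold higher. The inflammatory fibroblast list also went both ways, with 4 of 19 members higher and 4 lower (median 0.06, percentile 50.5, with a median of -0.30 under the authors' scaling alone). Serum amyloid Saa3 was 7.15-fold lower, Ly6c1 6.73-fold lower, Ptges 4.01-fold higher and Lif 3.59-fold higher. Lif read 10.2 in NF, just above the limit, and 32.6 in CAF, so its fold is imprecise. Il6 was near the limit on both arrays, at 21.3 in NF and 23 in CAF.

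The interferon response and antigen-presenting fibroblast lists were lower in CAF as well. In the interferon list 9 of 24 members were at least 2-fold lower and 2 higher (median -0.82, percentile 0.03). Gbp3, a guanylate-binding protein, was 11.8-fold lower, Rsad2 6.90-fold and the immunoproteasome gene Psmb8 5.94-fold, and Psmb9 was at least 6.67-fold lower. In the antigen-presenting fibroblast list 3 of 6 members were lower and 1 higher (median -1.21, percentile 0.58, or -1.11 with genes detected on 1 array at their bound). H2-DMb1 was 4.10-fold lower and Cd74, the invariant chain, at least 3.07-fold lower. The third lower member, Saa3 (7.15-fold), is a serum amyloid gene that is also on the inflammatory list. Slpi, a secreted protease inhibitor, was at least 33.9-fold higher. The antigen-presenting list was inside the range of random lists at a detection limit leaving 5% of background above it (median -0.77, percentile 3.17), at a limit 3 times as high (-0.60) and under the cyclic loess fit over all probes (-0.25, percentile 21.3). That fit also turned the direction of H2-DMb1 (1.05). The CAF array with these lower genes was the one with the higher mesothelial markers.

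Genes of the insulin-like growth factor axis were split between large rises and large falls in intensity. Of 16 measured 8 were at least 2-fold higher and 3 lower, with a median of 0.99 (percentile 100). Igf2, a fetal growth factor, was 21.2-fold higher and Igfbp2 at least 41.6-fold, beside Igfbp6. Igf1 was 4.26-fold lower and both its probes had this direction (-2.09 and -2.94). The TGF-beta list had 9 of 24 members higher and 5 lower (median 0.47, percentile 99.0, against percentile 94.0 under the cyclic loess fit over all probes). Follistatin (Fst) was at least 53.5-fold higher, while Tgfbi was 17.9-fold lower, Bmp4 14.1-fold lower and the BMP antagonist Grem1 9.82-fold lower. Other growth factors had 3 of 26 higher and 7 lower (median -0.24, percentile 9.15), with Egfr 5.68-fold higher, Angptl4 23.5-fold lower, Vegfc 18.7-fold lower and pleiotrophin (Ptn) at least 26.4-fold lower. In the JAK-STAT and SOCS list 2 of 23 members were higher and 6 lower (median -0.20, percentile 13.7). Socs3, a feedback inhibitor of cytokine signalling, was 3.93-fold lower, Il6ra 4.22-fold lower and Jak2 2.53-fold higher, with Il6ra higher (2.16) under the cyclic loess fit over all probes. Socs1 read 10.9 in NF, just above the limit, and 2.9 in CAF, which gives no fold. The mesothelial markers (11 of 11 at least 2-fold higher) were higher on the same CAF array as the insulin-like growth factor and TGF-beta lists.

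Cholesterol synthesis and glycolysis genes were lower in CAF. Of 18 measured cholesterol genes 11 were at least 2-fold lower and 0 at least 2-fold higher (median -1.29, percentile 0.0). Pmvk was 6.58-fold lower, Mvd 5.09-fold, Sc5d 3.92-fold and Lss 3.64-fold, all enzymes of the pathway. Of 18 glycolysis genes 5 were lower and 1 higher (median -0.57, percentile 0.09, with a median of -0.25 under 75th percentile scaling). Pdk1, a pyruvate dehydrogenase kinase, was 9.73-fold lower, Hk1 at least 4.02-fold lower, and the glucose transporter gene Slc2a3 at least 7.93-fold higher. Pfkl was 3.73-fold lower on its brighter probe and higher by 0.98 on a dim one. The reference gene list, which shares Gapdh and Pgk1 with glycolysis, was also lower (median -0.47, percentile 0.89, or 5.31 against unmatched random lists), and the mesothelial markers were higher on the same CAF array (median 2.76). The hypoxia list, which shares Pdk1, had 6 of 13 members lower and 0 higher (median -0.18, percentile 24.2, with a median of 0.06 under 75th percentile scaling), with Ddit4 4.75-fold and Adm 4.44-fold lower. Oxidative stress genes had 5 of 19 higher and 4 lower (median -0.23, percentile 12.8, with a median of 0.06 under 75th percentile scaling). Gsta4 was 6.64-fold higher and Nqo1 4.76-fold higher.

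**Figure D3:**
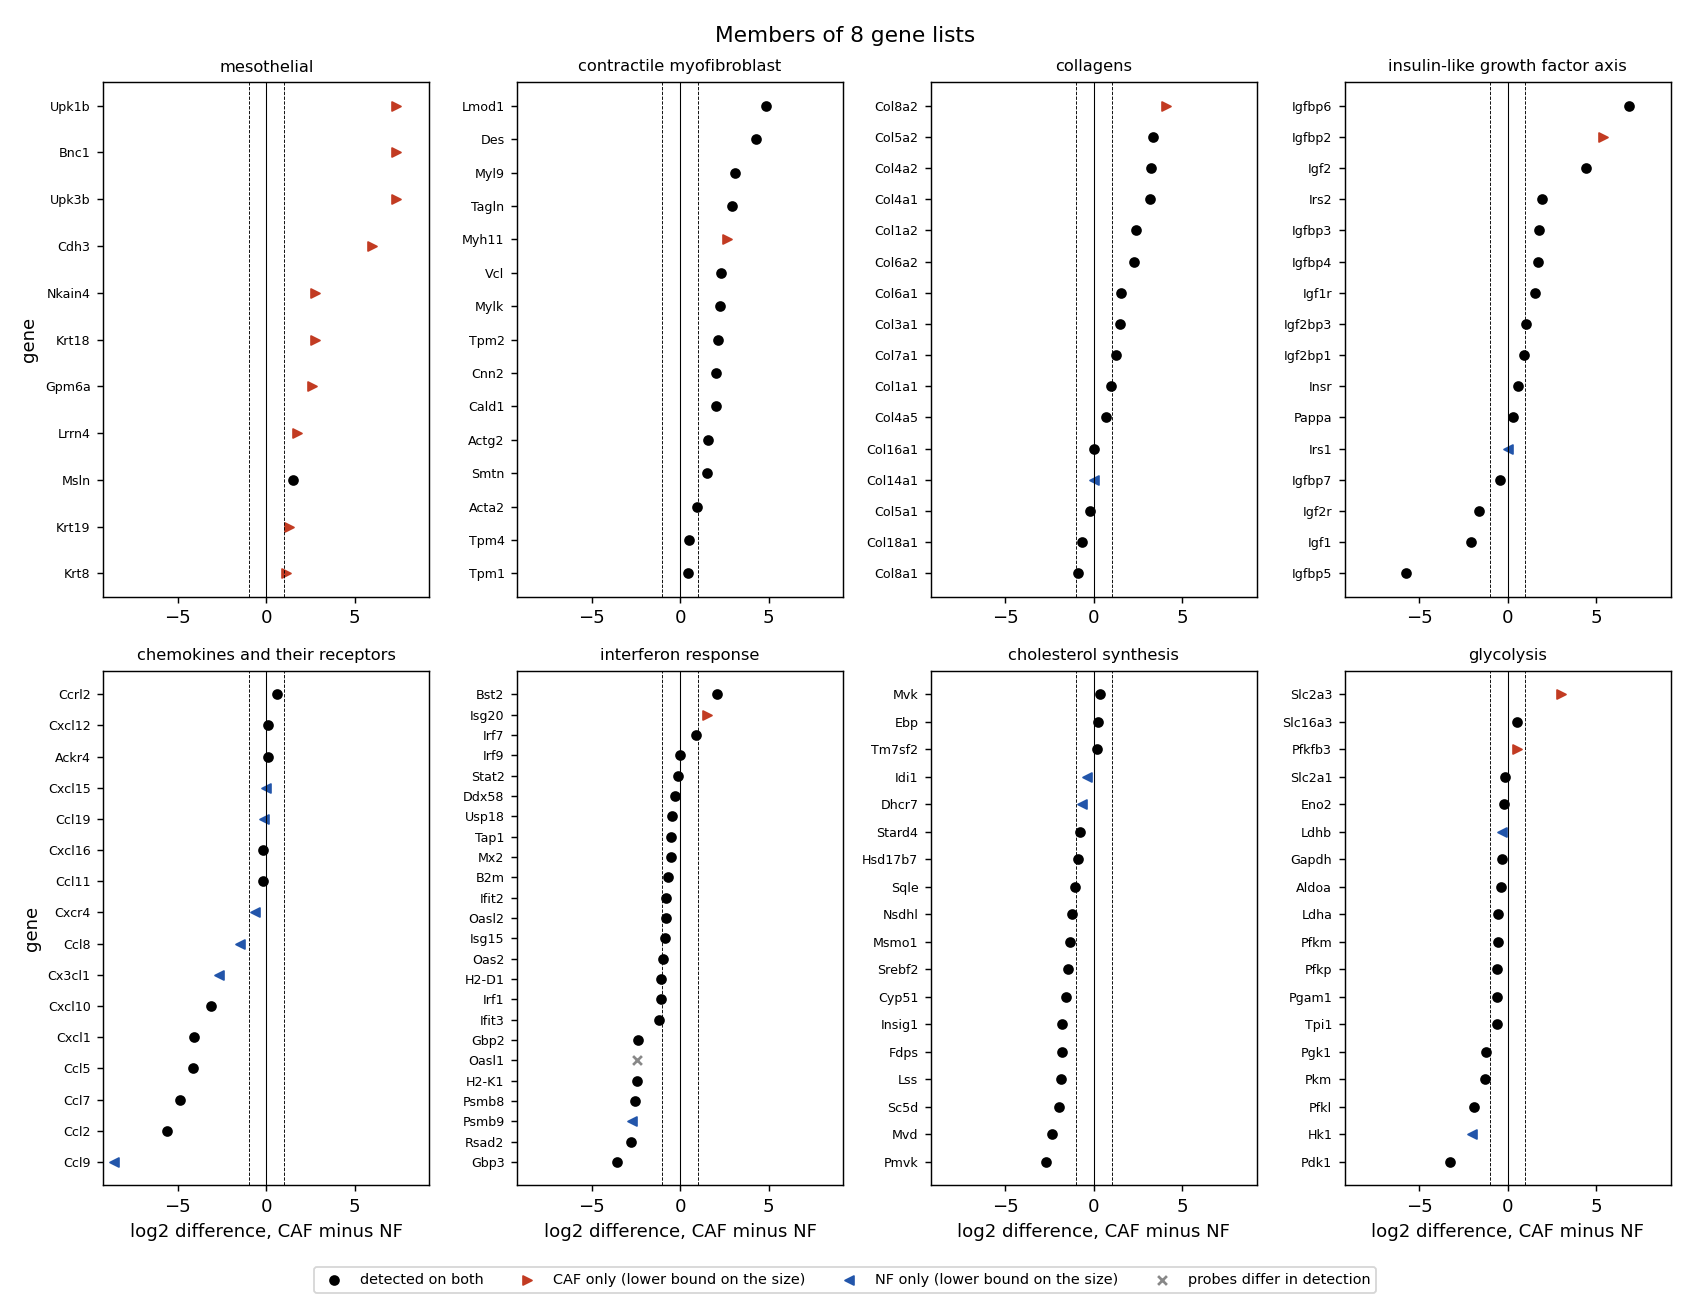
Log2 difference, CAF minus NF (x axes), of each measured member of 8 lists (y axes). Circles are genes detected on both arrays, triangles are lower bounds on the size for genes detected on 1 array, crosses are genes whose probes differ in detection, and dashed lines mark 2-fold; all 11 mesothelial markers lie beyond the upper dashed line and 11 of 18 cholesterol genes beyond the lower one.

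Cell-cycle genes differed little, whereas single cell-cycle inhibitors differed by several fold. Of 32 proliferation genes 1 was at least 2-fold higher, cyclin E1 (Ccne1, 3.74-fold), and 0 were lower (median -0.23, percentile 7.13, with a median of 0.03 under 75th percentile scaling). Among 19 kinase inhibitors and p53 targets 6 were higher and 3 lower (median -0.11, percentile 31.6, with a median of 0.06 under 75th percentile scaling and 0.48 under the cyclic loess fit over all probes). Cdkn2b was 5.94-fold lower, Cdkn2a differed by -3.41 and -3.44 (log2) on 2 probes and by 0.28 on a dim one, Cdkn1c was at least 11.7-fold higher and Plk2 4.82-fold higher. In the DNA methylation machinery 3 of 13 members were higher and 1 lower (median -0.07, percentile 41.6, with a median of 0.24 under 75th percentile scaling). Gadd45b was higher by 1.58 (log2), Gadd45g was 2.66-fold higher, and Mbd4 was at least 2.35-fold lower. Immediate early and heat shock genes had 2 of 21 higher and 2 lower (median -0.20, percentile 15.6, with a median of 0.06 under 75th percentile scaling), with Hspb1 7.46-fold higher. Unfolded protein response genes had 1 of 16 higher, Xbp1 (3.52-fold), and 1 lower, Dnajc3 (2.10-fold), with a median of 0.09 (percentile 66.2). Of 23 ribosomal protein genes 1, Rplp0, was lower (2.12-fold) and 0 were higher (median -0.15, percentile 18.9). This median was positive with the authors' scaling alone (0.08) and with 75th percentile scaling (0.42). Among 10 reference genes Pgk1 and Tbp were lower (2.38-fold and 2.10-fold) and the median was -0.47 (percentile 0.89). Their median ranged from -0.75 to -0.13 over the scalings, and its percentile was 5.31 against unmatched random lists. A dim probe of Pgk1 gave 0.28, and the other probes of Tbp gave -0.51, -0.40 and 0.00.

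Hox genes, which carry positional identity in fibroblasts, were lower in CAF. Of 19 measured 6 were at least 2-fold lower and 2 higher (median -0.54, percentile 1.24, or -0.49 with genes detected on 1 array at their bound). Hoxb5 read 2197.8 in NF and 169 in CAF (12.1-fold), Hoxa5 was 8.20-fold lower and Hoxa2 at least 26.6-fold lower, whereas Hoxd11 was at least 3.34-fold higher. On the same arrays 11 of 11 measured mesothelial markers were at least 2-fold higher in CAF. Of 19 acinar markers with a named probe only 4 were measured, and 3 of these 4 were at least 2-fold lower. Without a detection filter the Hox median was 0.0, since undetected members count as equal. In the stellate cell and retinoid list 3 of 9 members were higher and 4 lower (median 0.14, percentile 55.2, with a median of -0.19 under the authors' scaling alone). Crabp1, a retinoic acid-binding protein gene, was at least 24.5-fold lower and Aldh1a3 at least 7.05-fold higher. Complement genes had 3 of 11 higher and 4 lower (median -0.39, percentile 12.1). C4a was 23.3-fold and C4b 10.8-fold lower, and these near-identical genes can share signal. C2 was 14.8-fold higher and Cd55 at least 17.0-fold higher.

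Markers of further cell types were few and mostly dim. In the ductal and epithelial list 4 of 12 measured members were at least 2-fold higher and 1, Sox9, lower (median 0.69, percentile 94.7). The 4 higher members were keratin genes, 3 of them shared with the mesothelial list. Krt18 read 62.6 and Krt7 46.3 in CAF, both below the limit in NF. In the endothelial list 0 of 9 were higher and 2 lower (median -0.49, percentile 7.29), with Plvap at least 19.1-fold and Eng 2.82-fold lower. Flt1, the brightest endothelial marker, was close to equal (819.9 in NF and 784.2 in CAF, log2 difference 0.01), and Egfl7 was 1.61-fold higher. The acinar markers Rnase1, Cela1 and Amy2a5 were lower in CAF, at least 12.3-fold, 7.87-fold and at least 6.91-fold, of 4 measured and 19 with a named probe. Of the 4 measured, 3 were detected only in NF and could not count as higher in CAF. Of 2 measured glial markers Mbp was 5.26-fold higher and Ngfr 14.1-fold lower. Of 4 skeletal muscle markers 3 were higher, Des among them, with Acta1 2.94-fold and Mylpf at least 2.78-fold, though Acta1 was near equal (-0.09) under the cyclic loess fit over all probes. Of 3 adipocyte markers, 0 passed 2-fold in either direction, and Lpl was 1.44-fold higher. Of 11 lymphocyte markers with a named probe 1 was detected, Cd3e, at 29.3 in CAF. The endocrine markers Chgb and Ppy were each near the limit on 1 array, and 0 of 5 erythroid markers with a named probe were detected. Among sex-linked genes Xist, the X-inactivation RNA, was detected only in CAF on all its 4 probes (at least 52.2-fold), Kdm5d only in NF on 1 of its 2 probes (at least 3.82-fold) and Uty only in CAF on 1 of its 4 probes at 26.5.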

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

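Settings chosen after seeing the data were the detection limit 3 times as high, the offsets, quantile normalization before the floor, the bounds, and cyclic loess on probes detected on both arrays. The last was added after the designed cyclic loess over all probes had turned named genes around. Of the 13 lists that stood apart, 7 did so under all 13 settings run for lists (contractile, collagens, mesothelial, insulin-like growth factor axis, interferon, cholesterol and glycolysis). Cyclic loess over all probes gave 1869 genes at least 2-fold higher in CAF and a correlation of the arrays of 0.827. It left the antigen-presenting (-0.25) and TGF-beta (0.46) medians inside the random range and turned H2-DMb1 (1.05), Il6ra (2.16) and Acta1 (-0.0908). Its shifts differed by up to 6.00 (log2) among probes of like intensity, with 55.9% of probes tied at the floor on both arrays. In the added fit the 13 lists stayed outside the random range and the 143 named genes past 2-fold stayed past it in the same direction, while the inflammatory median, inside the range, turned to -0.05. Whether the ties cause the difference between the fits was not tested further. The antigen-presenting median also fell inside the range with a limit leaving 5% of background above it (-0.77) and with a limit 3 times as high (-0.60), and the cause was not tested. The reference genes did so against unmatched random lists (-0.47, percentile 5.31). With no detection filter the chemokine, Hox and pericyte medians were 0.0, because members below the limit on both arrays then count as equal. An offset of 50 gave 588 genes at least 2-fold higher and 490 lower. A 1.5-fold threshold gave 2075 and 1868, and a 3-fold threshold 445 and 365. Genes detected only in CAF numbered 453 with the limit 3 times as high, where fewer probes pass. The other 48 counts and correlations stayed within 1.5 times (counts) or 0.05 (correlation) of those reported. Of 143 named genes past 2-fold, 105 stayed past it in size under all those of the 11 settings run for genes that measured them. Direction was not part of this count. The 3 genes that cyclic loess over all probes turned changed direction, and H2-DMb1 and Il6ra were past 2-fold the other way there. No paired analysis was possible because each group has 1 array, and no replicate could be left out. The alternatives on background correction were not run, since they need the unused table, and the authors' value table was already the source of all values. Of 2071 genes past 2-fold, 632 had their dimmer value under 3 times the detection limit.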

Other observations

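The tests of epithelial, mesothelial and myeloid cells, of animal sex and of values near the detection limit below were chosen only after the results were seen. Outside the lists, and named here after their values were seen, several regulators were detected only in NF. The transcription factor genes Isl1, Osr2 and Twist2 read 1039.9, 748.5 and 735.4 in NF and were below the limit in CAF, at least 86.5-fold, 61.5-fold and 60.6-fold lower. The scavenger receptor gene Scara5 (at least 78.2-fold), the secreted protein gene Srpx2 (at least 87.9-fold) and the oxysterol hydroxylase gene Cyp7b1 (at least 51.0-fold) were lower in the same way. In CAF alone, the proprotein convertase gene Pcsk6 (at least 120-fold), Vat1l (at least 105-fold), Tmem108 (at least 83.7-fold) and the inflammatory caspase gene Casp1 (at least 64.2-fold) were detected.

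The mesothelial markers had the highest median of the 32 lists with a percentile (2.76), and values near the detection limit do not account for it, since 8 members stayed at least 2-fold higher with the limit 3 times as high. Epithelial tumour cells in the CAF preparation stay open, since 4 of 12 measured epithelial markers were at least 2-fold higher. All 4 were keratins. Of these, 3 are on both lists and read 20 to 62.6 in CAF, and Krt7, on the epithelial list only, read 46.3. With the limit 3 times as high 1 epithelial marker was at least 2-fold higher and 1, Sox9, the brightest in NF, was lower (39.5-fold at the limit used), and the keratins lie too near the limit to settle it. Mesothelial cells mixed into the CAF preparation, and CAF that themselves carry a mesothelial profile, both predict what was seen (11 of 11 measured markers at least 2-fold higher). They cannot be told apart with 1 array of RNA from a whole preparation. Of these 11 markers 10 count as measured only through their detection in CAF and could not count as lower, and 13 had a named probe. A difference between tumour-derived and normal fibroblasts may also lie behind it and was not testable without replicates.

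The chemokine genes were lower in CAF. The normalization between arrays does not account for it, since the list median closest to 0 over quantile, no further, 75th percentile and all-probe cyclic loess scaling was -0.78. Myeloid cells in the NF preparation stay open. Of 10 measured myeloid markers 3 were at least 2-fold lower in CAF (Cd14, Cd53 and Coro1a) and 2 higher. The brightest, Lyz1, read 503.7 in NF and 939.5 in CAF. With the limit 3 times as high 1 of the 21 markers with a named probe was lower and 0 were higher, too few to decide. Culture state, passage and the tumour origin also stay open and were not tested.

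Xist and Kdm5d were detected on opposite arrays, and both stayed so (2 of 2) when values near the detection limit were excluded with a limit 3 times as high. Cells from animals of different sex could give this, but of 3 Y-linked genes with a named probe 1, Uty, was detected on the array with Xist and 1, Kdm5d, on the other. The Uty signal rests on 1 of its 4 probes at 26.5 and that of Kdm5d on 1 of its 2 probes at 51.1. With the limit 3 times as high (31.5 in CAF) Uty was below the limit, and the bound for Kdm5d was under 2-fold. The labels give no sex, so this stays open, and a sex difference would be part of every CAF and NF comparison above.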
